A study of Saccharomyces cerevisiae with 31 samples.

How the data were processed

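RNA was measured in budding yeast, *Saccharomyces cerevisiae*, of 4 genotypes: wild type (WT) and strains carrying the spt6-1004, spt6-S8A or spt6-S8E allele of SPT6. Per the labels' protocols, cultures in rich glucose medium at 30 °C were diluted to an optical density of 0.2 and collected at 1. RNA came from an acid-phenol extraction, ribosomal RNA was depleted, ERCC spike-in RNA was added after that depletion, and stranded libraries were sequenced as paired-end reads. The 12 RNA libraries are 3 per genotype. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these samples, which can be technical. Another 19 samples, chromatin immunoprecipitations of Spt6 and of histone H3 with their inputs, were not analysed here.

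The authors' deposited tables hold their own comparisons of each mutant with WT, without values per library. Per the submitters' processing notes, cutadapt 1.10, STAR 2.5.2b, Salmon 0.8.1, DESeq2 1.14.1, bedtools 2.26 and SAMtools 1.3.1 were used with build sacCer3; their roles and order are not given in the sources used here. Per the file headers, each row gives a gene's base mean, a log2 fold change with its standard error, a Wald statistic, a p-value and an adjusted p-value. The log2 fold changes and standard errors are the authors' and compare the mutant with WT. The deposited Wald statistic is a score equal to the log2 fold change divided by its standard error, which was checked for every row. The deposited p-value is two-sided, and the authors' adjusted p-value follows the Benjamini-Hochberg method. Every deposited row has an adjusted p under 0.05, so a gene missing from a table either missed that threshold or was never adjusted, and its value is not known. In this text "called" means listed in the authors' deposited table of a mutant.

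Several properties of the tables were worked out from their values. The base mean times 12 was a whole number in all 694, 23 and 1 rows, with a tolerance of 1e-06, and the 23 genes shared by 2 tables had equal base means. One fit of all 12 libraries with size factors of 1, or values scaled and rounded before the fit, gives such base means. Their unit is not given in the sources used here. Standard errors of 30 of the 694 spt6-1004 genes lie under the smallest error that counting of whole reads would allow for an unshrunken fold change, so the fold changes look shrunken towards 0 and understate the changes of genes with low base means. The depth of each library is unknown, and no interval that needs it is given. How the spike-ins entered the authors' scaling is not given in the sources used here.

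The number of genes that entered each adjustment was recovered by inverting the Benjamini-Hochberg formula. It was 5668 for spt6-1004, 431 for spt6-S8A and 5668 for spt6-S8E. Adjusted p-values recomputed with these numbers equalled the deposited ones in 694 of 694, 23 of 23 and 1 of 1 rows. For spt6-S8E the number came from that 1 row, so its match holds by construction. The lowest base mean among spt6-S8A rows was 32.6, so its 431 genes were taken to be those above a minimum base mean. Tested on simulated data for the spt6-1004 comparison with 5668 genes, of which 200 were changed, the recovery returned the true number in 100% of 50 sets. In those sets 96.8% of the changed genes were called and 95.2% of the calls were changed genes. The list test found a changed list in 100% of 50 sets and called 1 of 900 tests of random lists. These percentages depend on the effect sizes chosen for the simulation. They are not the power of the authors' comparison or of the list tests on it.

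Gene names, coordinates and coding lengths came from a table of RefSeq genes of assembly R64, for which sacCer3 is another name; 689 of 694 identifiers in the spt6-1004 table matched it, and all of those in the other tables. Lengths in that table are multiples of 3 for 96.4% of genes, so they are coding lengths. No genome sequence was used. Paralogs with near-identical sequence can share reads, and their values are uncertain.

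Counts of called genes are the authors' calls with no new test. Overlap of spt6-S8A and spt6-1004 calls was tested with Fisher's exact test over the 431 genes. Differences between mutants used a z test from the deposited standard errors, taken as independent, with Benjamini-Hochberg adjustment; the shared WT libraries make the true error smaller. The direction of a gene list compared higher and lower calls inside and outside the list with Fisher's exact test, for lists with at least 5 called members. The share test compared called members with all other tested genes, per direction, taking all annotated members as tested. Coding length, distance to the chromosome end and base mean were compared between higher and lower genes by a permutation test with 100000 resamples. All tests were two-sided, and p-values were adjusted over the tests of a family.

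The tests, 29 gene lists and the rule for named genes were fixed before the data were examined. Named genes are the 10 largest increases and the 10 largest decreases in spt6-1004, every gene in a table of 25 or fewer, up to 4 called members per list by smallest adjusted p, genes in several tables, and SPT6, SPN1, the casein kinase 2 genes and the core histone genes. Others are named as chosen after their values were seen. Alternatives were an adjusted p under 0.01, an absolute log2 fold change of at least 1, base mean minimums of 10 and 100, named protein-coding genes alone, another background, correlated errors and means of log2 values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.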

Results

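Spt6 is a histone chaperone and transcription elongation factor that travels with RNA polymerase II and binds Spn1. The series asks what phosphorylation of Spt6 by casein kinase 2 does. RNA was compared between WT and 3 mutants, with 3 libraries for each of the 4 genotypes. The spt6-S8A allele replaces serines in Spt6 with alanine, which cannot be phosphorylated, and spt6-S8E replaces them with glutamate, often used to imitate phosphate. The spt6-1004 allele is a widely used mutant allele of SPT6, and all cultures were grown at 30 °C. How much Spt6 function it keeps at that temperature was not analysed here. The values below are the authors' log2 fold changes against WT with the standard error (SE) of their DESeq2 fit, so no value per library and no depth per library is given.

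The first comparison asks which transcripts depend on Spt6 in the spt6-1004 mutant. Of annotated list members, 65 of 96 general stress genes and 17 of 50 glucose-repressed genes were called higher. In the same way, 103 of 138 cytosolic ribosomal protein genes were called lower. The list tests follow. SER3, a serine biosynthesis gene whose promoter is normally kept off by transcription across it, was at 4.71 (SE 0.29, adjusted p = 5.85e-57, DESeq2) in the authors' deposited table, a 26.1-fold increase. It lies on chromosome V from 322686 to 324095 (R64), and the values refer to its coding gene. The authors' deposited table listed 694 genes, 12.2% of the 5668 adjusted: 319 were higher, with a median log2 fold change of 1.64, and 375 were lower, with a median of -1.29. Changes of at least 2-fold made up 295 of the higher and 307 of the lower genes.

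In the authors' deposited table the largest increase was that of SSA3, an Hsp70 chaperone gene, at 5.28 (SE 0.45, adjusted p = 3.49e-29). TKL2, a transketolase gene, was at 4.76 and RTN2 at 4.65 in the authors' deposited table. YDL218W stood at 4.62, GAD1, which encodes glutamate decarboxylase, at 4.58 and GND2 at 4.49 in the authors' deposited table. HSP12 at 4.32, the glycogen phosphorylase gene GPH1 at 4.11 and the phosphoglucomutase gene PGM2 at 3.99 completed the 10 largest increases in the authors' deposited table. The largest decrease in the authors' deposited table was that of YHB1, which encodes a flavohemoglobin, at -3.40. INA1 was at -2.64, SFG1 at -2.35 and PMA1, the plasma membrane proton pump gene, at -2.28 (SE 0.19) in the authors' deposited table. EFT2, a translation elongation factor gene, was at -2.24, RPL21A at -2.21, SCW4 at -2.18 and EGT2 at -2.12 in the authors' deposited table. RPL40B at -2.09 and RPL40A at -2.08 had the same base mean of 33.8 in the authors' deposited table. These near-identical paralogs can share reads and are uncertain, as are EFT2 and TDH1, which have close copies too.

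Of the 138 cytosolic ribosomal protein genes, 103 were lower and 0 were called higher in the authors' deposited table, with a median of -1.56 among those called. The direction differed from that of other called genes (Fisher's exact test, adjusted p = 2.79e-30), and 74.6% of the list was called lower against 4.92% of other tested genes (adjusted p = 1.05e-94). The most significant members in the authors' deposited table were RPL16B at -2.00 (SE 0.22), RPP0 at -2.05 (SE 0.24), RPL5 at -1.86 (SE 0.22) and RPS0B at -2.07 (SE 0.25). Of the 122 ribosome biogenesis genes, which build ribosomes rather than form them, 9 were lower and 0 higher (direction, adjusted p = 0.0148). That call ended at an adjusted p under 0.01 (0.0624) and at a log2 fold change of at least 1 (0.0511). Called members had a median base mean of 57.5. Among called nuclear genes with base means of at least 41, 40 were higher and 130 lower, so the direction test does not separate list from level. The share of biogenesis genes called lower, 7.38%, was not distinguishable from the 6.60% of other genes (Fisher's exact test, p = 0.711). The 0 called higher was fewer than expected (Fisher's exact test, adjusted p = 0.00619, or 0.0761 for calls at an adjusted p under 0.01), which level can affect too. UTP10 at -1.75, UTP20 at -1.34, RPA190 at -1.07 and NOG1 at -1.28 were the leading members in the authors' deposited table. The called share differed between ribosomal protein and biogenesis genes (Fisher's exact test, p = 1.51e-30). This test counts paralogs that can share reads as separate genes. Being called also depends on level, which is unknown for uncalled members.

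Of the 96 general stress response genes, 65 were higher and 0 lower in the authors' deposited table (direction, adjusted p = 1.82e-23), with a median of 2.40. HSP26 was at 3.85 (SE 0.27), GAD1 at 4.58 (SE 0.32) and SSA4 at 3.05 (SE 0.23) in the authors' deposited table. Heat shock factor chaperones had 11 of 28 members higher and 3 lower (direction, adjusted p = 0.0347), led by HSP26, HSP82 at 2.46, SSA4 and SSA3 in the authors' deposited table. Of these called chaperones, 6 are also in the stress list. Glucose-repressed carbon metabolism had 17 of 50 members higher and 1 lower (adjusted p = 0.000148). Its leading members in the authors' deposited table were ADH2 at 2.96, MLS1 at 2.70 and ICL1 at 2.35, and its 1 lower member was ALD6 at -1.41. Multidrug and oxidative stress genes had 9 of 37 higher and 0 lower (direction, adjusted p = 0.00344), with AHP1 at 1.06, GTT1 at 2.27 and SRX1 at 2.23 in the authors' deposited table. Called members of the glucose-repressed and multidrug lists had median base means of 4.33 and 4.25. Among called nuclear genes with base means up to 10.7, 143 were higher and 29 lower. The direction tests of both lists use called genes of all levels, so they do not separate list from level. Both shares called higher passed (Fisher's exact test, adjusted p = 1.26e-08 and 0.00108). Glycolysis and fermentation genes went both ways, with 7 higher and 13 lower of 26 (direction, adjusted p = 0.393), and both shares exceeded those of other genes (adjusted p = 0.0027 and 2.51e-08). At base means of at least 100, 12 members were called, all of them lower (direction, adjusted p = 0.00528). TDH1 was at 3.56, whereas ENO2 at -1.75, PDC1 at -1.46 and FBA1 at -1.47 were lower in the authors' deposited table.

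**Figure D1:**
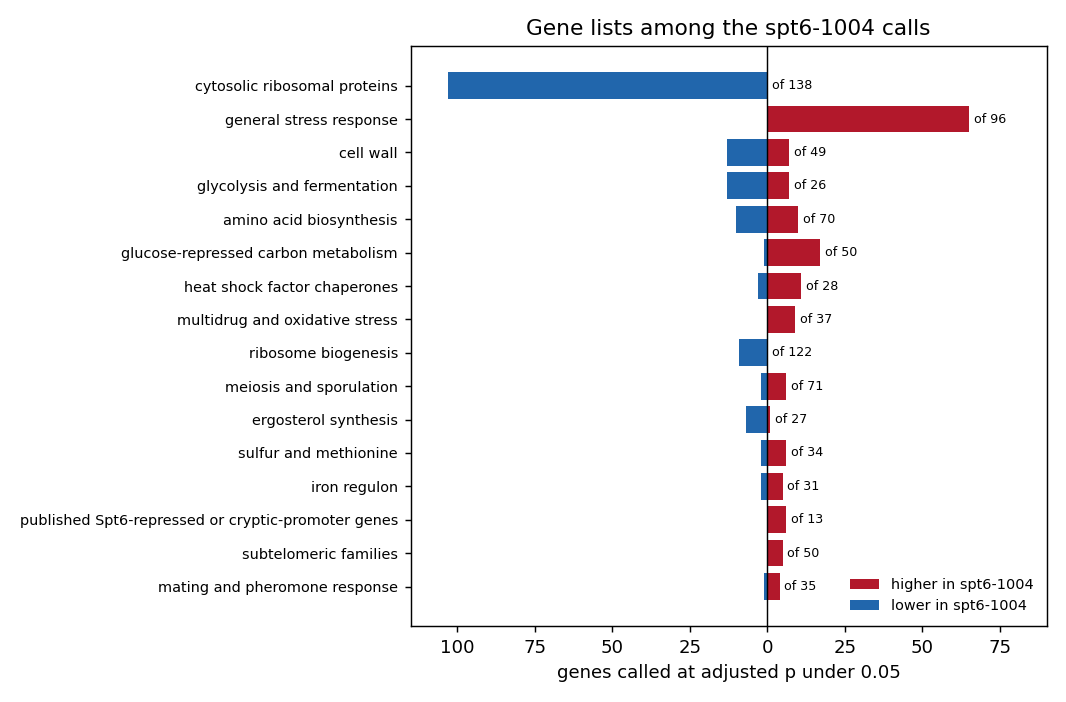
Number of genes called at adjusted p under 0.05 in spt6-1004 against WT for each gene list with at least 5 called members, lower genes to the left and higher genes to the right of 0; the text after each bar gives the annotated members. Ribosomal protein genes reach 103 lower and 0 higher, and general stress genes 65 higher and 0 lower.

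Genes published as repressed by Spt6 or carrying cryptic promoters had 6 of 13 members higher and 0 lower in the authors' deposited table (direction, adjusted p = 0.0245), a share of 46.2% against 5.53% of other genes (Fisher's exact test, adjusted p = 0.000297). With a log2 fold change of at least 1 the direction call ended (adjusted p = 0.0511), and at an adjusted p under 0.01 too few members were left to test it. The share passed in both settings (adjusted p = 0.00275 and 0.0439) but not at base means of at least 100. The 6 genes were SER3, ADH2, STE11 at 1.80 (SE 0.37), PHO8 at 1.00 (SE 0.32), VPS72 and FMP27, the last pair named after their values were seen. A sense total over a whole gene cannot tell a full-length transcript from one started inside it. Genes of subtelomeric families were higher in 5 of 50 cases and lower in 0 (direction, adjusted p = 0.0403), led by PAU23 at 3.54 and AAD14 at 2.02 in the authors' deposited table. At a log2 fold change of at least 1 this call ended too (adjusted p = 0.0511), and 3 of the 5, AAD14, AAD4 and AAD6, are also counted in the multidrug list. The share of subtelomeric genes called higher was not distinguishable from that of other genes (Fisher's exact test, adjusted p = 0.454). Their called members had a median base mean of 3.75, a level at which most called genes were higher. Ergosterol synthesis genes were called lower in 7 of 27 cases (share, adjusted p = 0.00683), with ERG11 at -1.56 and ERG13 at -1.46 in the authors' deposited table, and 1 member was higher (direction, adjusted p = 0.135). At an adjusted p under 0.01 the list had 7 lower and 0 higher and passed the direction test (adjusted p = 0.0385). Cell wall genes had 13 of 49 lower (share, adjusted p = 0.000104) and 7 higher, with CTS1 at -1.84 and GSC2 at -1.50 in the authors' deposited table. Amino acid biosynthesis genes split into 10 higher and 10 lower of 70, and the higher share exceeded that of other genes (adjusted p = 0.0215), a call that ended at an adjusted p under 0.01 (0.0505). LYS1 at 2.91, SNZ1 at 3.04 and THR1 at -1.89 were among them in the authors' deposited table. Sulfur and methionine genes had 6 higher and 2 lower of 34 (higher share, adjusted p = 0.0399), with MET6 at 2.57 in the authors' deposited table.

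The remaining lists passed no test run on them, and those with fewer than 5 called members had the share tests alone. The iron regulon had 5 higher and 2 lower of 31, including FIT3 at 2.49 and FET3 at -1.40 in the authors' deposited table. Meiosis and sporulation had 6 higher and 2 lower of 71, mating and pheromone response 4 and 1 of 35, and the phosphate regulon 3 and 1 of 17, with PHO84 at 3.06 in the authors' deposited table. Hexose transporters had 3 higher and 1 lower of 19, with HXT3 at 3.24 and HXT4 at -1.25 in the authors' deposited table. Respiratory chain and tricarboxylic acid cycle genes had 3 higher and 1 lower of 50, and thiamine and vitamin B6 genes 2 and 1 of 23. Cell cycle and DNA replication genes had 2 higher and 1 lower of 49, and purine biosynthesis 1 and 1 of 17. The proteasome list had 1 of 34 higher, its transcription factor RPN4 at 1.76 in the authors' deposited table, and flocculins 1 of 6 lower, FLO9 at -1.64. Elongation factors and histone chaperones had 2 higher and 2 lower of 30: CHD1 at 1.51, SPT2 at 1.38, NAP1 at -0.84 and NHP6A at -1.27 in the authors' deposited table. Among 11 histone genes HTB2 alone was listed, at -1.36 (SE 0.31, adjusted p = 0.000303) in the authors' deposited table. SPT6, SPN1, CKA1, CKA2, CKB1 and CKB2 were listed in none of the authors' tables, and neither were the other core histone genes or the 6 genes of the silent cassette list. The retrotransposon list matched 0 annotated genes and was not evaluated. Adjusted over the list alone, at least the same number of members passed in each list except cell cycle, where it was at least 2 of 3. Of all called genes, 364 were in no list, 163 of them higher and 201 lower.

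Genes called higher had low mean levels: their median base mean was 12.1 against 30.9 for lower genes (permutation test, adjusted p = 3e-05 from a p of 1e-05, the smallest that the resamples can give). Calling alone can give such a difference. Base mean averages all 12 libraries, of which 3 are spt6-1004, so it is not independent of the change in that mutant. For genes raised many-fold, such as TKL2 at 27.1-fold, the spt6-1004 libraries can supply most of it. At base means up to 10.7, calls were mostly increases, with 143 higher and 29 lower. Their median coding length was 1501.5 bp in 308 nuclear genes against 1186.5 bp in 372 lower genes (permutation test, adjusted p = 0.00072). Without ribosomal protein genes the difference turned to -100.5 bp (permutation p = 0.318). By base mean it was 672 bp (permutation p = 0.00012) up to 10.7, 583.5 bp (p = 1e-05, the smallest that the resamples can give) up to 21.1, 466 bp (p = 0.0113) up to 40.9 and -361.5 bp (p = 0.182) above; these settings were chosen after seeing the data. The difference in median distance to the chromosome end did not pass (permutation test, adjusted p = 0.533), but as a difference of mean log2 values it was -0.32, closer for higher genes (permutation p = 0.00134). Within 20000 bp of an end lay 15 of 308 higher genes (4.87%) and 2 of 372 lower genes (0.54%; Fisher's exact test, p = 0.000298), against 4.22% of annotated genes. The contrast thus lies in the small share of lower genes, as the higher share was near the annotated one. It was not matched for base mean, and few called genes with low base means were lower, so it does not separate position from level. This distance was set after seeing the data.

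The next comparison asks what loss of the phosphorylated serines does. In spt6-S8A, SER3 had the largest increase and the smallest adjusted p, at 3.46 (SE 0.29, adjusted p = 4.81e-30, DESeq2) in the authors' deposited table. The authors' deposited table listed 23 genes, 14 higher and 9 lower, which is 5.34% of the 431 adjusted. SSA3 at 2.12 (SE 0.45), SPI1 at 1.57 (SE 0.34), GAD1 at 1.44 (SE 0.35) and TDH1 at 1.32 (SE 0.33) followed SER3 in the authors' deposited table. PCS60 was at 1.25 (SE 0.26), with HBT1 at 0.99, RPN4 at 0.93, NTH1 at 0.89 and SSA4 at 0.88, in the authors' deposited table. YGP1 at 0.84, MVD1 at 0.76, GLK1 at 0.75 and the vacuolar protease gene PEP4 at 0.73 made up the rest of the increases in the authors' deposited table. The largest decrease in the authors' deposited table was that of TAL1, the transaldolase gene, at -1.32 (SE 0.27, adjusted p = 0.000145). RPL40A was at -0.82, EFB1 at -0.76, ALD6 at -0.76, the RNA helicase gene DED1 at -0.76 and FET3 at -0.74 in the authors' deposited table. PTR2 was at -0.68, RPL16B at -0.64 and PMA1 at -0.61 in the authors' deposited table. The general stress list held 7 of the 14 higher genes, and the ribosomal protein list 2 of the 9 lower ones. Adjusted over all 5668 genes, an alternative chosen after seeing the data, at least 6 pass: SER3, SSA3, SPI1, GAD1 and PCS60 higher and TAL1 lower. For the other 17 this depends on p-values of genes outside the 431, which were not analysed here.

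The spt6-S8E mutant, with glutamate at these positions, had 1 listed gene. SER3 was at 2.75 (SE 0.30, adjusted p = 9.31e-17, DESeq2) in the authors' deposited table, a 6.71-fold increase over WT. The 5668 genes adjusted leave a p of at least 1.76e-05 for any other gene, which is a Wald statistic of at most 4.29 in size. Of the 22 other spt6-S8A genes, 4 had a p under that limit in their own comparison, so the single call in spt6-S8E does not show that other genes were unchanged there.

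SER3 was listed for all 3 mutants. It was 1.24 lower in spt6-S8A than in spt6-1004 on the log2 scale (95% interval of spt6-1004 minus spt6-S8A, 0.44 to 2.04; z test, adjusted p = 0.00349) and 1.96 lower in spt6-S8E than in spt6-1004 (1.15 to 2.77, adjusted p = 5.82e-06). The difference between spt6-S8A and spt6-S8E, 0.72, had an interval of -0.10 to 1.53 (adjusted p = 0.0841). With errors correlated by 0.5 through the shared WT libraries the p of that difference was 0.0146, so the call depends on this assumption.

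All 23 genes called in spt6-S8A were also called in spt6-1004, in the same direction. Independent lists would share 1.95 of the 14 higher genes among the 431 (Fisher's exact test, p = 2.45e-13) and 3.70 of the 9 lower genes (p = 0.000294). In either direction 12.6 would be shared (Fisher's exact test, p = 8.03e-07), since at least 55.0% of the 431 genes were called in spt6-1004. The spt6-1004 calls counted were the 237 with base means of at least 32.6, and the 431 genes may hold more. The expected numbers are therefore minimums, and the p-values the smallest possible. Both comparisons share their WT libraries, and part of the excess may come from them; without values per library the controls could not be split. With both mutants simulated as unchanged, the mean number of genes called in both was 0, against the 23 observed. An unchanged spt6-S8A beside a changed spt6-1004 was not simulated, so this mean does not bear on that case. It is the closer case, as at least 55.0% of the 431 genes were called in spt6-1004. With both unchanged, 303 of 4000000 draws passed the weakest Wald statistic of the shared genes in each table, and 100% of these had the same sign. The shared direction of the 23 genes therefore does not tell a shared effect from shared controls. The covariance of the fold changes was 2.68 across these 23 genes, against 0.0377 simulated from shared controls, and their correlation was 0.922 against 0.486. The observed values are across genes chosen for being called, which are not independent replicates, whereas the simulated values had no such choice. That choice can raise both values, so this contrast does not by itself tell a shared effect from shared controls.

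Changes were smaller in spt6-S8A for 23 of the 23 shared genes, with a median ratio of the log2 fold changes of 0.489 and a range of 0.268 to 0.946. The difference passed its test for 14 of them (z test, Benjamini-Hochberg over 23 genes). For the other 9, which include TAL1, PCS60, MVD1 and SPI1, it did not pass; the interval for PCS60 ran from -0.82 to 0.63. With errors correlated by 0.5 through the shared WT libraries 18 passed, adding ALD6, FET3, RPN4 and PEP4 (adjusted p from 0.00932 to 0.0419). The proton pump gene PMA1 had the lowest ratio, with -0.61 in spt6-S8A and -2.28 in spt6-1004 in the authors' deposited table.

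**Figure D2:**
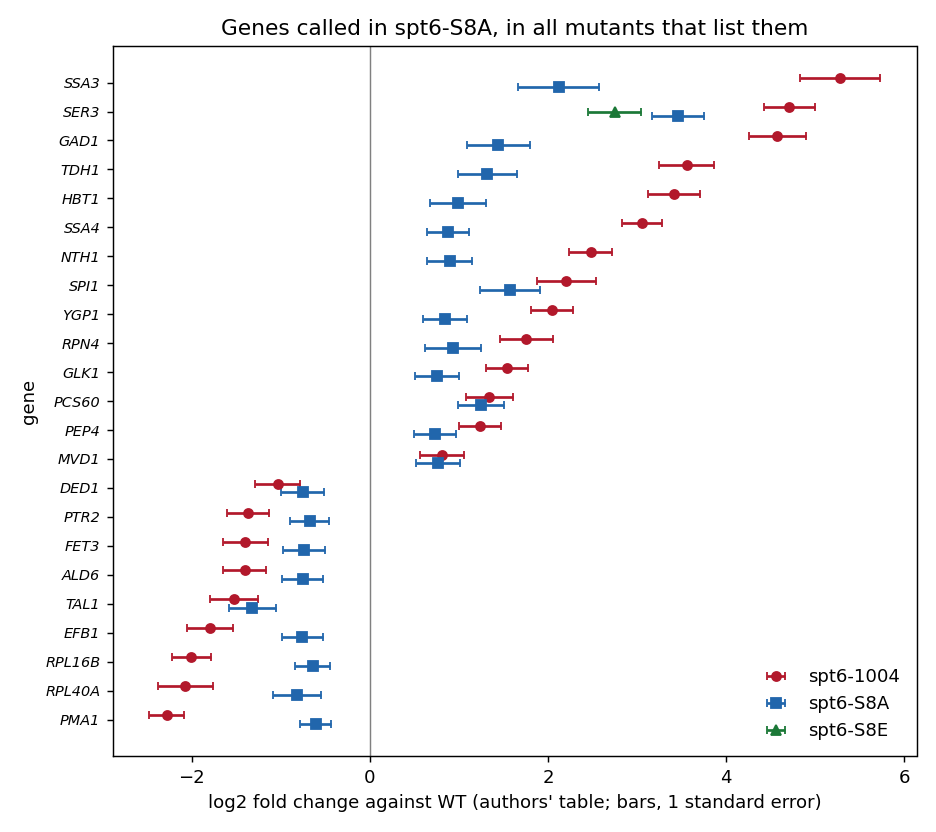
The log2 fold change against WT, with bars of 1 standard error from the authors' tables, for the 23 genes called in spt6-S8A, shown for each mutant whose table lists them. SER3 appears for all 3 mutants at 4.71, 3.46 and 2.75, and each spt6-S8A value lies closer to 0 than the spt6-1004 value.

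**Figure D3:**
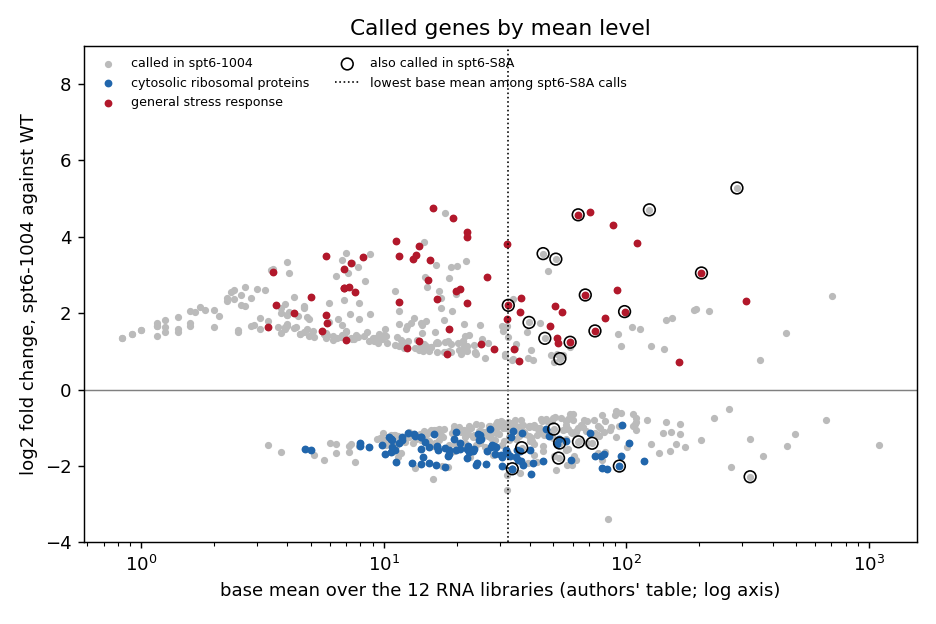
The log2 fold change in spt6-1004 against base mean over the 12 RNA libraries (log axis) for the 694 called genes, with ribosomal protein and general stress genes coloured, genes also called in spt6-S8A circled, and a dotted line at the lowest base mean among those, 32.6. Of the called genes, 457 lie below the line, where the spt6-S8A table lists none.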

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

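All tests of explanations in this part were chosen after the results were seen, as were the SER3 differences that involve spt6-S8E, whereas the differences between spt6-S8A and spt6-1004 were planned. The log2 fold changes of 14 genes differed between these 2 alleles. As spt6-S8A minus spt6-1004 on the log2 scale, the difference was -3.16 for SSA3, -3.13 for GAD1, -2.43 for HBT1, -2.24 for TDH1 and -2.18 for SSA4. It was -1.58 for NTH1, -1.24 for SER3, -1.20 for YGP1 and -0.78 for GLK1. Among genes lower in both mutants it was 1.67 for PMA1, 1.36 for RPL16B, 1.26 for RPL40A, 1.04 for EFB1 and 0.69 for PTR2. Each passed a z test of the difference at an adjusted p under 0.05, and RPL40A can share reads with a near-identical paralog. SER3 also differed between spt6-1004 and spt6-S8E, by 1.96.

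The 23 calls in spt6-S8A against 1 in spt6-S8E were weighed against the number of genes adjusted. Over the 5668 genes used for spt6-S8E at least 6 of the 23 pass (SER3, SSA3, SPI1, GAD1, PCS60 and TAL1), whatever the p-values of the genes the authors filtered out, which argues against this number as the whole cause. As part of the cause it stays open, since those p-values, not analysed here, decide whether the other 17 pass. A larger effect of spt6-S8A, the biological explanation the design names, stays open: the SER3 difference between these mutants did not pass with independent errors (adjusted p = 0.0841), and spt6-S8E values of the other genes were not analysed here.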

How the results depend on the processing

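No paired analysis was possible because the authors' tables hold no values per library; for the same reason the replicate block, leaving out each replicate, edgeR and other splits of the samples were not run. A base mean minimum of 100 left 49 genes called in spt6-1004, 4 in spt6-S8A, 2 lists with a direction among the 3 still testable, and 4 share tests, each with fewer genes by construction. In spt6-S8A an adjusted p under 0.01 left 8 genes, a log2 fold change of at least 1 left 7, and adjustment over all tested genes, added after seeing the data, left at least 6, with the other 17 undecided. With that log2 minimum 5 lists passed the direction test, among 15 testable. The SER3 difference of 0.72 between spt6-S8A and spt6-S8E passed with correlated errors (p = 0.0146), also added later. By the permutation test, the coding length difference was 220.5 bp (p = 0.0834) at an adjusted p under 0.01 and 0.10 (p = 0.207) as a difference of mean log2 values. It turned to -361.5 bp at base means of at least 41, against 672, 583.5 and 466 bp in the 3 lower ranges, and to -100.5 bp without ribosomal protein genes, all added after seeing the data; in the last case the short, lower ribosomal protein genes are removed by construction, and for the others the cause was not tested. As a difference of mean log2 values, distance to the chromosome end passed at -0.32 (permutation p = 0.00134), and the cause was not tested. The other 26 settings of main results kept their side of the threshold or stayed within 1.5 times the main count. Among gene lists and named genes, 158 settings kept a call and 39 ended it without a reversal. Another 12 left an uncalled list uncalled, and 2 brought a direction past the threshold, for glycolysis and ergosterol genes. For named genes a setting only applies a stricter limit to the authors' own p-values. At an adjusted p under 0.01, 86 named spt6-1004 genes kept their call and 10 lost it. Those genes were named for large changes or small adjusted p, so keeping a call was partly fixed by that choice. At a base mean of at least 100, uncalled cell wall genes turned to 40% higher, above the other calls, and 4 shares of lists that had passed fell to 0%. The unknown depth and the tables' limit at an adjusted p of 0.05 leave the values of uncalled genes open.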

Other observations

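Apart from the planned share test of ribosome biogenesis genes, the tests in this part were chosen after the values were seen, as were most genes named. Mitochondrially encoded genes appeared among the spt6-1004 calls: 8 of 19 were listed in the authors' deposited table, 7 higher and 1 lower. COX1 was at 2.05, ATP6 at 2.14 and COX2 at -1.06 in the authors' deposited table, and 5 of the higher features are intron-encoded reading frames within COX1, at 1.64 to 2.10, which overlap it and are not separate observations. Neighbouring genes rose together more often than permuted labels gave: 32 adjacent pairs were both higher against a mean of 15.5 in 10000 permutations (adjusted p = 0.0036). In tandem pairs it was 19 against 7.46 (adjusted p = 0.0024), as in HBT1 and FMP45 or ALD3 and ALD2, in convergent pairs 4 against 3.97, and in divergent pairs 9 against 4.04 (adjusted p = 0.158). Some tandem neighbours are related copies that can share reads.

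Called ribosomal protein genes were lower and called stress genes higher in spt6-1004. One scaling factor per library moves all genes by the same log2 amount, so it cannot by itself put these lists, fixed before the data were examined, on opposite sides of 0. No such factor alters their distance: the 10th percentile of called stress genes, 1.20, lies 2.37 above the 90th percentile of called ribosomal protein genes, -1.17, on the log2 scale, values taken over called members whose directions were already known, and a smaller shift of all genes is not excluded. A general growth or stress program of the mutant could account for both, and it was tested on ribosome biogenesis genes, whose share called lower was not distinguishable from that of other genes (Fisher's exact test, p = 0.711). This leaves it open, since all 9 called members were lower and the values of the uncalled ones were not analysed here; a direct effect of Spt6 on these genes was not tested.

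LEU2 was at 3.12 (SE 0.53, base mean 3.42) and URA3 at 1.34 (SE 0.46, base mean 0.833) in spt6-1004 in the authors' deposited table. Regulation of the whole leucine and pyrimidine pathways is argued against: 0 of 16 other pathway genes were called higher, and 4 were lower, with URA2 at -1.15, ILV6 at -1.04, ILV2 at -0.94 and URA7 at -0.85 in the authors' deposited table. A difference in marker genotype between strains is a candidate explanation, since both genes are common selection markers. Of 7 such markers searched, 3 were called higher, the third being MET17 at 1.28 in the authors' deposited table, and 4 were not listed. MET17 had a base mean of 21.2 and belongs to the sulfur and methionine list, which had 6 higher and 2 lower. Its increase is therefore not counted for a marker difference. If WT lacked LEU2 and URA3, their fold changes would be among the highest for their base mean. Of called genes within 1.25-fold of it, 2 of 29 were above LEU2 (median 1.95), as this needs, but 4 of 5 above URA3, 6 in all. For URA3 this comparison cannot decide. Its base mean was the lowest among spt6-1004 calls, so no neighbour had a lower one, and fold changes look shrunken at low base means. The unmatched identifier YPR160W-A had the same base mean and log2 fold change. By the bound first set, URA3 lying under the median of 1.45 of its 5 neighbours spoke against this explanation. For the same reason that reading is not kept. The bound was then changed to require more than 1 standard error, 0.46. Low counts and the strains' full genotypes, not analysed here, keep the explanation open.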
